A study of Mus musculus with 6 samples.

How the data were processed

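RNA was measured in 6 libraries of cultured mouse spermatogonia. The cells are GS cells, germline stem cell cultures that grow from testis germ cells and keep the properties of spermatogonial stem cells, and both alleles of Cdkn1c, the gene of the cell cycle inhibitor p57, carried loxP sites. Per the labels, 3 libraries came from cells with the floxed alleles (control) and 3 from cells of that genotype with Cre recombinase, delivered by an adenovirus (p57 KO). Per the labels' protocols, the RNA was taken 2 days after infection from cells that had been dissociated with trypsin and passed over a Sephadex column. The libraries were made with a stranded mRNA kit and sequenced as single reads of 76 bp. The growth protocol gives an age of 3 days for the mice and the design text 10 days. The strain and the kit also have different names in different labels. No age, strain or kit name is therefore used below. Whether the control cells received a virus without Cre is not given in the sources used here, nor is the part of the gene that Cre removes.

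The deposited values are raw counts per gene, with 1 column per library and no normalization by the authors. The submitters' processing notes name bcl2fastq 2.20, cutadapt 3.4, HISAT2 2.2.1, HTSeq 2.0.2 and the mouse genome build mm10. The gene annotation, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Counts of genes that overlap a gene on the other strand are therefore uncertain, and so are those of near-identical copies such as Hspa1a and Hspa1b, the histone genes and the ribosomal protein genes. Of the 32285 gene identifiers in the table, 32235 were found in release 21 of the GENCODE mouse annotation (M21, the same build), 31502 of them with the same symbol. Positions were taken from that annotation.

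Total counts per library lay between 15662833 and 17893671, and 23200 genes had a count in at least 1 library. Genes with low counts were removed with edgeR's filterByExpr at its default settings, which left 14814 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with the group as the only term, robust dispersion estimates and Benjamini-Hochberg adjustment over the tested genes. A gene was called changed at an adjusted p under 0.05, and "rose" and "fell" are used for such genes. Levels are normalised read counts in CPM, each library's counts scaled to a common total, after TMM, given as mean ± SD over 3 libraries. A fold change is given as log2, p57 KO against control, with its standard error (SE). The common biological coefficient of variation was 4.35%, so that small fold changes of well expressed genes pass the test.

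The test was tried on simulated data with the means, dispersions and library sizes of these libraries, over 14814 genes of which 200 were changed. It recovered 49.3% of the genes changed 1.2-fold, 70.1% of those changed 1.5-fold and 92.4% of those changed 2-fold, with 17 false calls among 158.

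Before the data were examined, 26 gene lists were written down, for pathways and for cell types that the culture could hold. Each list was tested as a set with limma's camera on log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the 26 lists. The calls were compared with camera's estimated correlation and with the rotation test fry. In each list the members past the threshold were counted with the adjustment over all tested genes and with the p-values adjusted over the list alone. The rule for naming genes was also fixed before: Cdkn1c; the 12 genes with the largest rise and the 12 with the largest fall among called genes of at least 2 CPM whose groups did not overlap, leaving out unnamed gene models; and up to 4 members of smallest p from each list. Genes whose values are given outside this rule were chosen after the values were seen. Among them are Trp53, Hspa1b, Fn1 and Vim.

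The alternatives fixed before were RLE size factors, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts (at least 1 CPM in 3 libraries), the replicate number as a block, each library left out in turn, and a test against a fold of 1.2. Added after the data were seen were a model with the mean log2 CPM of the fibroblast and feeder cell markers as a covariate, called the fibroblast score here, and counts without the genes of chromosome 7. Replicates of a group were compared in pairs by a chi-square test over genes with at least 20 counts. Every pair differed by more than sampling noise, so no library was counted as a duplicate. The chi-square per degree of freedom was 1.69 to 2.12 for control pairs and 2.87 to 5.97 for p57 KO pairs. The labels do not say whether the replicates were separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.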

Results

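The libraries came from cultured spermatogonia with floxed alleles of Cdkn1c, with and without Cre, and the comparison asks what changed in the RNA of these cells 2 days after the gene was targeted. There were 3 control and 3 p57 KO libraries. The control libraries held 16460019, 16979459 and 15662833 counts and the p57 KO libraries 15940375, 16417794 and 17893671, so that depth did not separate the groups.

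The RNA of the targeted gene was lower in every p57 KO library. Cdkn1c, an imprinted gene that encodes the cyclin-dependent kinase inhibitor p57, lies on the minus strand of chromosome 7 from 143458339 to 143461050 (mm10). Its level was 20.7 ± 0.782 CPM in control (SD, n = 3) and 8.89 ± 0.486 CPM in p57 KO (SD, n = 3), which is 42.9% of the control level. The log2 fold change was -1.22 (SE 0.09, edgeR adjusted p = 4.07e-09). The counts were 311 to 364 per control library and 138 to 155 per p57 KO library. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. The labels give neither the deleted part of the gene nor the share of cells in which it was deleted, so the remaining counts can come from RNA outside the deletion or from cells that kept the gene. The gene overlaps Gm44732 on the other strand.

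**Figure D1:**
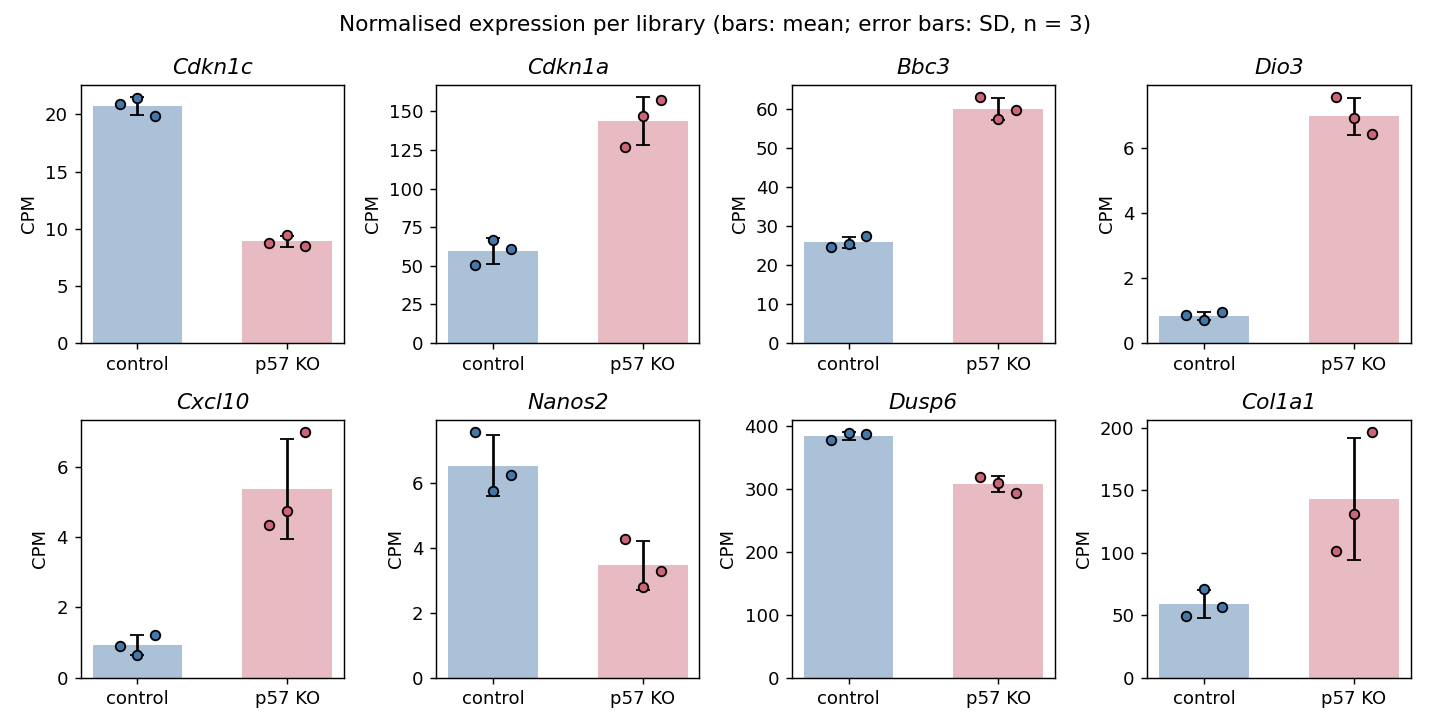
Normalised expression in CPM of 8 genes in the 3 control and the 3 p57 KO libraries; points are libraries, bars are means and error bars are SD. Cdkn1c lay at 20.7 CPM in control and 8.89 CPM in p57 KO, and Col1a1 (adjusted p = 0.0626) varied most between the p57 KO libraries.

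Expression differed widely between the groups, mostly by small amounts among the genes that fell. In p57 KO 1725 genes rose and 1725 fell, 3450 together or 23.3% of the 14814 tested. Rises were larger: the median log2 fold change was 0.43 for genes that rose and -0.18 for genes that fell. At least a 2-fold change was seen for 397 genes that rose and for 7 that fell. Tested against a fold of 1.2 in place of no change, 469 genes passed in edgeR, 414 higher and 55 lower. In a model that also holds the fibroblast score 374 genes passed, 225 higher and 149 lower, and 346 of the 374 were among the 3450. Of 113 genes named by rule besides Cdkn1c, 35 kept direction and call in that model. The 113 include markers that are averaged into the score, such as Tagln and Thy1.

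**Figure D2:**
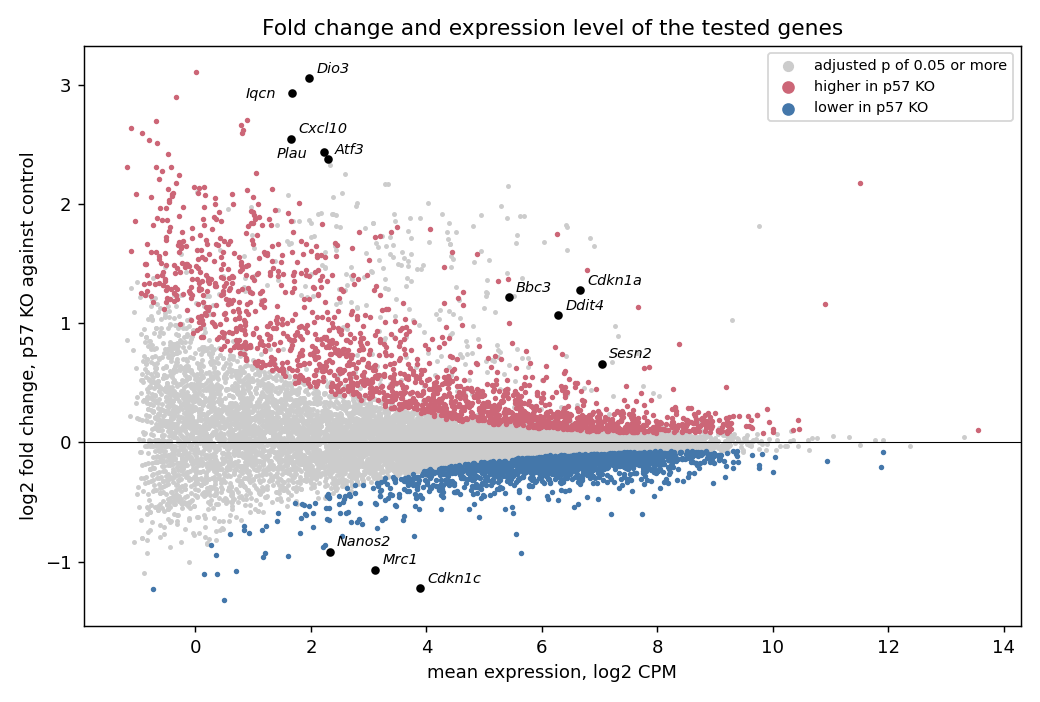
Log2 fold change (p57 KO against control) of each tested gene against its mean expression in log2 CPM; red and blue mark genes with an adjusted p under 0.05. Large changes were mostly rises, with 397 genes at least 2-fold higher and 7 at least 2-fold lower.

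Among called genes with an established name, a mean of at least 2 CPM over the 6 libraries and groups that did not overlap, the largest rise was that of Dio3, which encodes an enzyme that inactivates thyroid hormone. It went from 0.838 ± 0.127 to 6.98 ± 0.567 CPM (SD, n = 3 in each group), a log2 fold change of 3.05 (SE 0.20, edgeR adjusted p = 6.87e-10). Iqcn rose by 2.93, the chemokine gene Cxcl10 by 2.54, Plau, which encodes urokinase, by 2.43, and the stress-induced transcription factor gene Atf3 by 2.37, all as log2 fold changes. Adssl1, Ccer1, Slc14a1, Hspb8, Nrn1, Ifit1 and Adamtsl5 followed among these genes, with log2 fold changes from 1.93 (Adamtsl5) to 2.26 (Adssl1). Most of these genes were near 1 CPM in control. Leaving out single libraries, 3 of them lost their call in edgeR at log2 fold changes of similar size. Plau had 2.28 (adjusted p = 0.0986) without control replicate 1, 2.32 (0.0935) without control replicate 3 and 2.43 (0.0568) without p57 KO replicate 2. Slc14a1 had 1.81 (0.0686) without control replicate 1 and 1.89 (0.0724) without control replicate 2. Hspb8 had 1.92 (0.143), 2.19 (0.0738) and 1.92 (0.133) without control replicates 1, 2 and 3, and 1.92 (0.0741) without p57 KO replicate 2. With the fibroblast score in the edgeR model 7 of them lost their call: Adamtsl5 had 0.36 (adjusted p = 0.826), Hspb8 0.40 (0.71), Nrn1 0.67 (0.569), Slc14a1 0.71 (0.602), Plau 0.90 (0.124), Adssl1 1.03 (0.293) and Ifit1 1.29 (0.071).

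By the same limits on level and overlap, the deepest fall after Cdkn1c was that of Mrc1, which encodes the mannose receptor, from 11.7 ± 0.775 to 5.56 ± 0.21 CPM (SD, n = 3 in each group), a log2 fold change of -1.07 (SE 0.12, edgeR adjusted p = 1.08e-06). Gdf10 had a log2 fold change of -0.97 and Pde4c of -0.93. Nanos2, an RNA-binding regulator that keeps spermatogonia undifferentiated, had -0.92 (SE 0.17, edgeR adjusted p = 0.000477). Gt(ROSA)26Sor, Snhg14, Sidt1, Atoh8, Mypop, Trp63 and Zfp607a fell with values from -0.88 (Gt(ROSA)26Sor) to -0.74 (Zfp607a). Gt(ROSA)26Sor overlaps Thumpd3, Snhg14 overlaps Ube3a, and Nanos2 overlaps Gm45058, each on the other strand. The adjusted p of Zfp607a was 0.0504 in edgeR without p57 KO replicate 2 and 0.11 in DESeq2. In edgeR with the fibroblast score 7 of these genes lost their call: Gdf10 had -0.29 (adjusted p = 0.845), Nanos2 -0.42 (0.595), Trp63 -0.43 (0.642), Zfp607a -0.72 (0.474), Atoh8 -0.82 (0.134), Snhg14 -0.86 (0.163) and Gt(ROSA)26Sor -0.96 (0.0909).

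Targets of p53, the transcription factor that responds to DNA damage and other stress, rose together. Of 31 tested targets, 26 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.50. Bbc3, which encodes the cell death inducer PUMA, rose from 25.8 ± 1.41 to 60.1 ± 2.84 CPM (SD, n = 3 in each group; log2 fold change 1.22, SE 0.06, edgeR adjusted p = 3.14e-12). Cdkn1a, the gene of the kinase inhibitor p21, rose from 59.5 ± 8.23 to 144 ± 15.3 CPM (log2 fold change 1.27, SE 0.14, edgeR adjusted p = 0.00583). Sesn2, Plk2 and Zmat3 rose by 0.66, 1.45 and 0.55 as log2. The RNA of p53 itself, Trp53, had a log2 fold change of -0.06 (edgeR adjusted p = 0.252). The list passed camera (adjusted p = 2.57e-15), and had an adjusted p = 0.363 with an estimated correlation. With the fibroblast score as a covariate 14 of the 31 rose, the median was 0.31 and camera's adjusted p was 8.4e-13.

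Among 23 apoptosis regulators, 7 rose and 2 fell (also 7 and 2 adjusted over the list alone), with a median log2 fold change of 0.09. Besides Bbc3, the risers included Bax and Pmaip1, which promote cell death at the mitochondrion, and Apaf1, a component of the apoptosome. Their log2 fold changes were 0.35, 0.42 and 0.38. The list did not pass camera (adjusted p = 0.12), and 4 to 7 members rose in the fits that left out 1 library. The fibroblast score as a covariate turned the median to -0.02, with 4 members that rose. Bbc3, Bax and Pmaip1 are also in the list of p53 targets.

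The lists of CDK inhibitors, of cyclins, CDKs, RB and E2F factors, of DNA replication and of DNA repair did not pass camera. Of 7 CDK inhibitors, 2 rose (Cdkn1a and Cdkn2a) and Cdkn1c fell; adjusted over the list alone 4 rose and 1 fell. Cdkn2a had a log2 fold change of 0.33 (SE 0.07, edgeR adjusted p = 0.00742), with an adjusted p of 0.0508 without control replicate 1 and 0.0584 without p57 KO replicate 2, and with the fibroblast score it had -0.014 (0.976). Of 27 cyclins, CDKs, RB and E2F factors, 3 rose and 7 fell (4 and 7 adjusted over the list alone), among them Cdk4 with -0.17, E2f1 with -0.21, E2f5 with -0.30 and Ccnd2 with -0.13. Of 34 DNA replication genes, 1 rose (Gmnn, 0.19) and 6 fell, including Rfc5 with -0.15, Rrm1 with -0.10 and Mcm7 with -0.10 (1 and 5 adjusted over the list alone). Of 24 DNA repair and checkpoint genes, 0 rose and 5 fell (0 and 6 adjusted over the list alone), including Fanci with -0.26 and Blm with -0.14. Leaving out 1 library, 1 to 3 CDK inhibitors and 3 to 5 genes of the cyclin list rose, and 2 to 6 replication genes and 2 to 5 repair genes fell. In edgeR with the fibroblast score 1 CDK inhibitor rose, and Cdkn1c and 1 gene of the cyclin list fell, while the replication and repair lists lost their calls. The folds of Blm (-0.18) and Gmnn (0.21) did not shrink then, and Rrm1 with -0.09 and Cdk4 with -0.16 were about as before. Smaller folds than before were those of Fanci with -0.21, Rfc5 with -0.08, Mcm7 with -0.07, E2f1 with -0.10, E2f5 with -0.22 and Ccnd2 with -0.11. In edgeR, Gmnn and Blm had an adjusted p of 0.0766 and 0.0586 without control replicate 3, and Mcm7 had 0.0569 without control replicate 1, 0.0751 without control replicate 2 and 0.0938 without p57 KO replicate 3. Blm had 0.0545 in DESeq2. Camera's adjusted p was 0.216, 0.417, 0.282 and 0.114 for these lists, in the order given, and with no filter on low counts it was 0.024 for the repair list. For the CDK inhibitors camera pointed up and fry down, and for the cyclin list the mean of 0.0026 lay above 0 and the median of -0.02 below.

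Mitotic genes were slightly higher. Of 27, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.14. The number that rose was 18 without p57 KO replicate 1, 2 without control replicate 3 or without p57 KO replicate 2, and 7 to 9 without 1 of the other libraries. Cenpf, a kinetochore gene, rose from 324 ± 6.74 to 374 ± 21.9 CPM (SD, n = 3 in each group; log2 fold change 0.21, SE 0.04, edgeR adjusted p = 0.000684). Cenpe, Ndc80 and Plk1 had 0.15, 0.20 and 0.24. The mean level of the list was 0.02 log2 above the control mean in p57 KO replicate 1, against 0.21 and 0.14 in replicates 2 and 3. Camera called the list (adjusted p = 0.00373), but not without p57 KO replicate 2 (adjusted p = 0.11), and gave an adjusted p = 0.572 with an estimated correlation. Fry did not call it (adjusted p = 0.194). In edgeR, Cenpe had an adjusted p of 0.054 without control replicate 3, and Ndc80 and Plk1 had 0.0603 and 0.0567 without it and 0.0585 and 0.0566 without p57 KO replicate 2. Given the fibroblast score as a covariate, the median of the list was 0.0034, and camera's adjusted p was 0.72.

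Genes of spermatogonial self-renewal were lower as a group. Of 30 tested, 16 fell and 2 rose (18 and 4 adjusted over the list alone), with a median log2 fold change of -0.16. In the fits that left out 1 library 13 to 17 fell and 1 to 4 rose. Id4, which marks the most stem-like spermatogonia, fell from 111 ± 3.83 to 76.8 ± 4.49 CPM (SD, n = 3 in each group; log2 fold change -0.54, SE 0.04, edgeR adjusted p = 1.33e-08). Zbtb16, the gene of the transcription factor PLZF, had -0.34, Sall4 -0.31 and Etv5, a target of GDNF signalling, -0.20. The GDNF receptor genes Ret and Gfra1, chosen after their values were seen, had -0.34 and -0.15. All members given here were lower, and the 2 that rose are not among them. The list passed camera (adjusted p = 0.000335), with an adjusted p = 0.363 with an estimated correlation. With the fibroblast score as a covariate 3 of the 30 fell, the median was -0.10 and camera's adjusted p was 0.024.

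Other germ cell lists did not pass camera. Of 16 differentiation genes, 4 rose and 3 fell (also 4 and 3 adjusted over the list alone). Kit, the receptor of differentiating spermatogonia, rose from 5.59 ± 0.62 to 8.16 ± 1.01 CPM (SD, n = 3 in each group; log2 fold change 0.55, SE 0.14, edgeR adjusted p = 0.00633; 0.0502 without p57 KO replicate 2), while Dnmt3a and Sohlh2 had -0.21 each. Of 19 general germ cell genes, 0 rose and 5 fell (also 0 and 5 adjusted over the list alone), including Dazl, an RNA-binding protein gene needed for germ cell development, with -0.25 and Nanos3 with -0.45. Of 29 meiosis genes, 4 rose and 2 fell (also 4 and 2 adjusted over the list alone), with Hspa2 at 0.66 and Tex15 at 0.18 against Sycp1 and Stag3 at -0.16. Of 11 pluripotency genes, 1 rose (Klf5, 0.62) and 3 fell (1 and 4 adjusted over the list alone), among them Pou5f1 and Dppa4 with -0.19 and -0.20. Pou5f1 had an adjusted p of 0.11 in edgeR without control replicate 1, 0.0921 without p57 KO replicate 2 and 0.059 without p57 KO replicate 3. Camera's adjusted p was 0.764, 0.0971, 0.612 and 0.296 for these lists. The general germ cell list passed downwards with limma-voom (adjusted p = 0.035), with no filter on low counts (0.023) and without p57 KO replicate 1 (0.039). In the fits that left out 1 library 3 to 5 general germ cell genes and 1 to 3 pluripotency genes fell, and 2 to 5 differentiation genes and 3 to 6 meiosis genes rose. The model with the fibroblast score left 1 differentiation and 1 meiosis gene higher, 1 general germ cell and 1 meiosis gene lower, and ended the pluripotency calls. Klf5 then had 0.63 and Tex15 0.17, about as before, while Pou5f1 had -0.0093, Dppa4 -0.06, Nanos3 -0.11, Kit 0.22, Dnmt3a and Sohlh2 -0.11 and Stag3 -0.13.

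The response genes of ERK signalling, which GDNF and FGF drive in these cells, parted into genes that fell and genes that rose. Of 26, 9 rose and 12 fell (9 and 14 adjusted over the list alone), and leaving out 1 library 5 to 9 rose and 7 to 12 fell. Dusp6, a feedback phosphatase of ERK, fell from 385 ± 6.19 to 308 ± 12.5 CPM (SD, n = 3 in each group; log2 fold change -0.32, SE 0.03, edgeR adjusted p = 1.46e-07). Fosl1, Ier3 and Myc rose by 0.86, 0.52 and 1.58. The median of -0.10 and camera (down, adjusted p = 0.754) differ in sign from the mean of 0.25 and fry (up). Of 17 targets of BMP, TGF-beta, WNT and YAP signalling, 5 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.156). The risers included the BMP-responsive genes Id1, Id2 and Id3, with log2 fold changes of 0.94, 2.08 and 0.44. Id2 had few counts, with 0.584 CPM in control and 2.52 CPM in p57 KO. Leaving out 1 library, 4 to 7 targets rose and at most 2 fell. In edgeR with the fibroblast score 1 of the 17 rose, Id1 had 0.45 (adjusted p = 0.267) and Id3 0.35 (0.0741), and of the ERK response genes 4 rose and 2 fell.

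Interferon response genes rose together. Of 28 tested, 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.56. Cxcl10 rose from 0.924 ± 0.284 to 5.37 ± 1.43 CPM (SD, n = 3 in each group; log2 fold change 2.54, SE 0.25, edgeR adjusted p = 4.04e-07). Ifit1, Isg15 and Bst2, which encode antiviral proteins, rose by 1.94, 1.24 and 0.42. The list passed camera (adjusted p = 8.98e-10), with an adjusted p = 0.363 with an estimated correlation. Given the fibroblast score as a covariate, 3 of the 28 rose, the median was 0.22 and camera's adjusted p was 0.0002.

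Stress genes rose in part. Of 23 genes of the integrated stress and unfolded protein response, 8 rose and 0 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.117, and 0.046 with limma-voom). Ddit3, the gene of the transcription factor CHOP, rose from 5.63 ± 0.872 to 10 ± 0.41 CPM (SD, n = 3 in each group; log2 fold change 0.83, SE 0.13, edgeR adjusted p = 8.15e-05), while the chaperone genes Calr and Hspa5 had 0.15 and 0.13. Given the fibroblast score, 1 of the 23 rose, and Ddit3 had 0.69 (edgeR adjusted p = 0.0978). Of 10 heat shock genes, 3 rose (Hspa1a 0.74, Hspb1 0.91 and Hspa8 0.10) and 0 fell (also 3 and 0 adjusted over the list alone). Hspa1a shares sequence with Hspa1b, which had 0.10 (edgeR adjusted p = 0.236). Camera called the heat shock list (adjusted p = 0.027), but not without control replicate 2 (0.056), p57 KO replicate 1 (0.057) or p57 KO replicate 3 (0.071). It had an adjusted p = 0.363 with an estimated correlation and 0.12 with the fibroblast score as a covariate, where the median was 0.05 against 0.06 without it, Hspa8 had 0.10 and Hspb1 0.72.

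Metabolic lists did not pass camera. Of 25 genes of glycolysis and hypoxia, 9 rose and 3 fell (10 and 4 adjusted over the list alone; adjusted p = 0.133), with 3 to 11 risers when 1 library was left out, the angiogenic factor gene Vegfa at 0.66 and the glucose transporter gene Slc2a1 at -0.27. In edgeR with the fibroblast score the 9 risers lost their call, and Vegfa had 0.065 (adjusted p = 0.925). Tpi1, at 0.35 without the score, then had 0.062 (0.863). The fold of Ankrd37 did not shrink, with 1.01 (0.207). Of 23 cholesterol synthesis genes, 3 rose and 2 fell (also 3 and 2 adjusted over the list alone; adjusted p = 0.571), the 2 being Dhcr7 with -0.40 and Srebf2 with -0.11 (edgeR adjusted p = 0.0516 without control replicate 3). At most 2 cholesterol genes rose when 1 library was left out. Of the risers, Insig1 (0.09) lost its call in 4 of these fits and Tm7sf2 (0.65) in 5, both in DESeq2 (adjusted p = 0.111 and 0.217) and Tm7sf2 in limma-voom (0.0554). The 3 risers also lost it with the fibroblast score, where Tm7sf2 had 0.69 and Insig1 0.05. Of 12 mitochondrially encoded genes, 1 rose (mt-Co1, 0.10) and 3 fell (mt-Nd2 -0.21, mt-Nd5 -0.08 and mt-Nd6 -0.31; also 1 and 3 adjusted over the list alone; adjusted p = 0.156, and 0.03, downwards, with no filter on low counts). mt-Nd5 and mt-Nd6 overlap on opposite strands. The fall of mt-Nd6 was lost in edgeR without control replicate 1, control replicate 2 and p57 KO replicate 2 (adjusted p = 0.0933, 0.201 and 0.148), and was not called by limma-voom (0.067) or DESeq2 (0.129). That of mt-Nd5 was lost without control replicates 2 and 3 and p57 KO replicates 2 and 3 (adjusted p = 0.0609, 0.189, 0.184 and 0.0577). With the fibroblast score 1 mitochondrially encoded gene rose and 1 fell, and the median was -0.03 against -0.11 without it. In that edgeR model mt-Nd5 had -0.04 (adjusted p = 0.818) and mt-Nd6 -0.59 (0.0772).

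Imprinted genes, of which Cdkn1c is 1, moved both ways. Of 45 tested, 11 rose and 8 fell (14 and 9 adjusted over the list alone), with a median of 0.11 and a camera adjusted p of 0.133 (0.039, upwards, without p57 KO replicate 1). Leaving out 1 library, 10 to 14 rose and 4 to 8 fell, and with the fibroblast score 1 rose and 2 fell. Dio3 and Igf2r rose, by 3.05 and 0.29, and Cdkn1c and Nap1l4 fell. Nap1l4, which lies from 143513579 to 143549106 on chromosome 7, had 299 ± 5.35 CPM in control and 229 ± 4.1 CPM in p57 KO (SD, n = 3 in each group; log2 fold change -0.38, SE 0.03, edgeR adjusted p = 3.93e-09). Among other genes of that region, chosen after their values were seen, H19 had 0.39 (edgeR adjusted p = 0.0678), Igf2 0.10 (0.51) and Kcnq1ot1 -0.06 (0.707). Others near Cdkn1c passed in both directions. Osbpl5 rose by 0.73 (edgeR adjusted p = 0.000632), Lsp1 by 0.57 (0.00177) and Tnfrsf23 by 1.69 (0.0444). Cars had -0.23 (0.00114) and Nadsyn1 -0.40 (0.00106), and Dhcr7 there fell too. Igf2r overlaps Airn on the other strand.

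**Figure D3:**
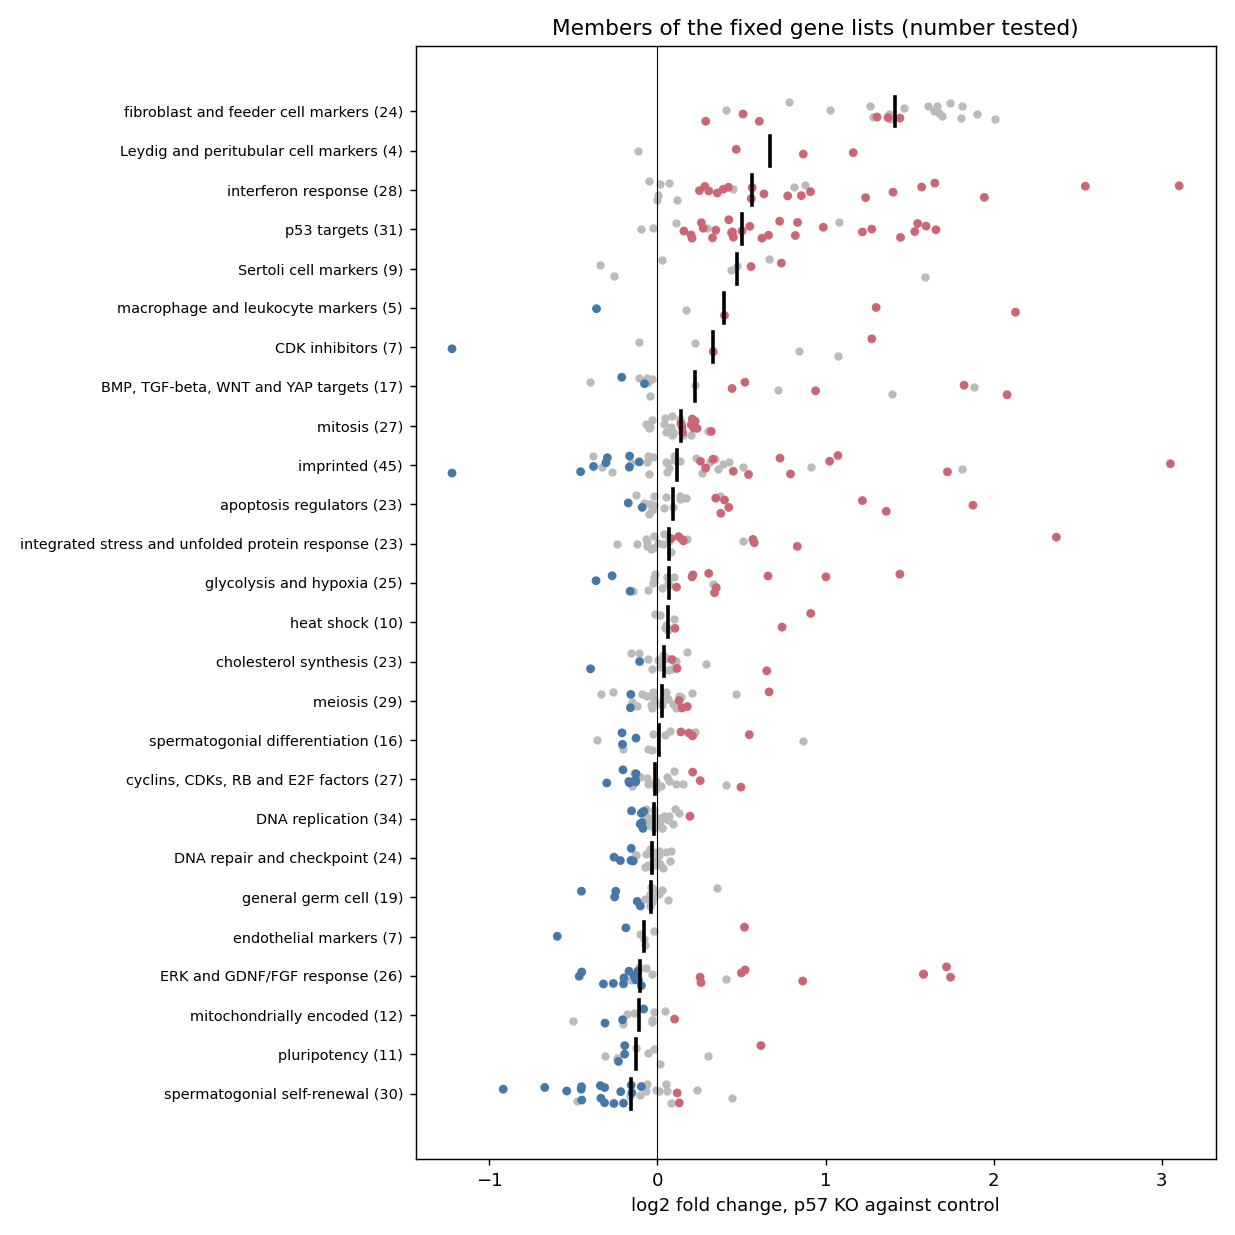
Log2 fold change (p57 KO against control) of the members of the 26 gene lists, sorted by the median, which is the black bar; red and blue points rose or fell at an adjusted p under 0.05 and grey points did not pass. The medians ran from -0.16 for spermatogonial self-renewal to 1.41 for fibroblast and feeder cell markers.

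Markers of fibroblasts and feeder cells, the supporting cells on which such cultures are commonly grown, were higher in p57 KO and varied between its libraries. Of 24 markers, 6 rose and 0 fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 1.41. The number that rose was 16 without p57 KO replicate 1, 2 without control replicate 3, 3 without control replicate 1 and 4 to 7 without 1 of the other libraries. Tagln and Acta2, which encode contractile proteins, rose by 1.44 and 1.31. The collagen gene Col1a1, chosen after its values were seen, had 58.9 CPM in control and 143 CPM in p57 KO (log2 fold change 1.28, SE 0.33, edgeR adjusted p = 0.0626). The mean log2 CPM of the list, relative to the control mean, was -0.20, 0.37 and -0.18 in control replicates 1 to 3 and 0.69, 1.28 and 1.83 in p57 KO replicates 1 to 3. The fibroblast score differed between the groups alongside the higher p53, interferon and mitotic genes and the lower self-renewal genes. The list passed camera (adjusted p = 2.93e-09), with an adjusted p = 0.452 with an estimated correlation of 0.85. Acta2 had an adjusted p of 0.0778 in edgeR without control replicate 3.

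Markers of other testis, blood and vessel cells moved both ways. The filter on low counts left 9 of 16 Sertoli, 4 of 12 Leydig and peritubular, 5 of 14 macrophage and leukocyte and 7 of 10 endothelial markers. Of 9 Sertoli cell markers 2 rose and 0 fell (Krt18 with 0.74 and Clu with 0.56). Of 4 Leydig and peritubular markers 3 rose and 0 fell (Igfbp3 1.16, Des 0.87 and Myh11 0.47). These 3 did not include Leydig cell genes of the list such as Star, Cyp17a1 and Insl3. Of 5 macrophage and leukocyte markers 3 rose, among them Lyz2 with 2.13 and Cd68 with 0.40, and 1 fell (Coro1a, -0.36). Lyz2 had few counts, with 0.38 CPM in control and 1.71 CPM in p57 KO. Of 7 endothelial markers 1 rose (Tek, 0.52) and 2 fell (Cdh5 -0.60 and Kdr -0.19). The counts were the same adjusted over the list alone. With the fibroblast score in the model, 1 Sertoli marker kept its rise and the other 3 lists lost their calls, many at folds of similar size. Cdh5 then had -0.60, Kdr -0.21, Tek 0.48, Coro1a -0.35, Cd68 0.45, Lyz2 1.62, Des 0.78 and Myh11 0.59, while Igfbp3 had 0.47 and Clu 0.10. The medians were -0.10 for the endothelial list (-0.08 without the score) and 0.45 for the macrophage and leukocyte list (0.40 without it). Camera's adjusted p was 0.156, 0.117, 0.157 and 0.159, and with no filter on low counts it was 0.022 for the macrophage and leukocyte list, upwards, then with 14 members. Clu, Igfbp3 and Myh11 lost their call in edgeR without single libraries, with adjusted p of 0.0579, 0.0802 and 0.22 without control replicate 1 and 0.0648, 0.0711 and 0.0552 without control replicate 3. Clu and Myh11 also lost it without p57 KO replicate 2 (0.0742 and 0.158), and Myh11 without control replicate 2 (0.0827) and p57 KO replicate 1 (0.0837). Myh11 was also not called by limma-voom (adjusted p = 0.0606) or DESeq2 (0.213). As a sign of RNA composition, the ribosomal RNA region transcripts Gm26917 and Gm42418 took 0.101%, 0.1% and 0.116%, and 0.12%, 0.11% and 0.125%, of the counts in the control libraries. In the p57 KO libraries they took 0.543%, 0.416% and 0.465%, and 0.286%, 0.245% and 0.259%.

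**Figure D4:**
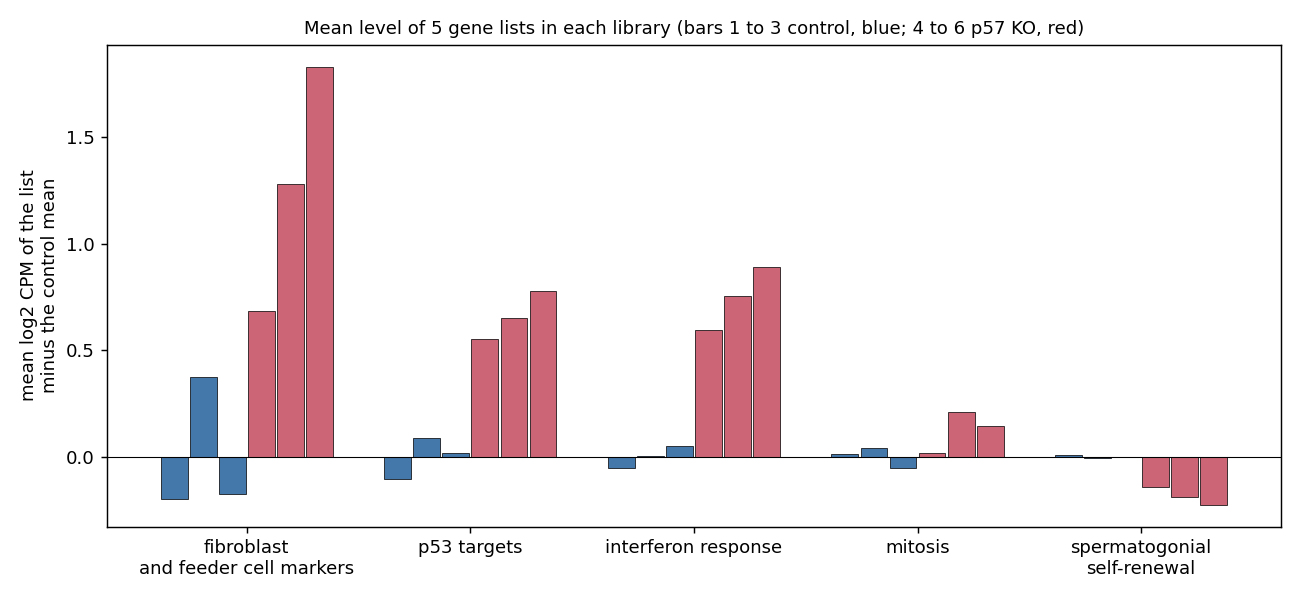
Mean log2 CPM of 5 gene lists in each library, relative to the mean of the control libraries; blue bars are control and red bars p57 KO, each in the order of replicates 1 to 3. The fibroblast and feeder cell markers lay at 0.69, 1.28 and 1.83 in p57 KO, and the p53 targets at 0.55, 0.65 and 0.78.

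Genes that fell were gathered on chromosome 7, a pattern noticed after the values were seen. Of 345 changed genes on this chromosome 105 rose and 240 fell (69.6% fell), while 1725 rose and 1725 fell over all tested genes. Chromosome 16 had the next highest share of falls, with 45 that rose and 75 that fell (62.5%). Among genes over 32 CPM from position 50000000 to its end, 260 in number, the median log2 fold change was -0.14, and it lay below that of the other chromosomes by 0.11 log2 (difference -0.11, 95% bootstrap interval over genes -0.13 to -0.10). The shift was not even: from 60 to 70 Mb, 12 genes had a difference of -0.02, and 50% of them lay below the median of the other chromosomes. Nearer the centromere the difference was -0.01 (-0.03 to 0.01). Each p57 KO library showed the shift of the whole segment, with differences of -0.12, -0.11 and -0.10 from the control libraries. Genes named by rule in this segment are Cdkn1c, Nap1l4, Dhcr7, Fanci, Blm, Rrm1, Coro1a and Snhg14, which fell, and Plk1, which rose.

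**Figure D5:**
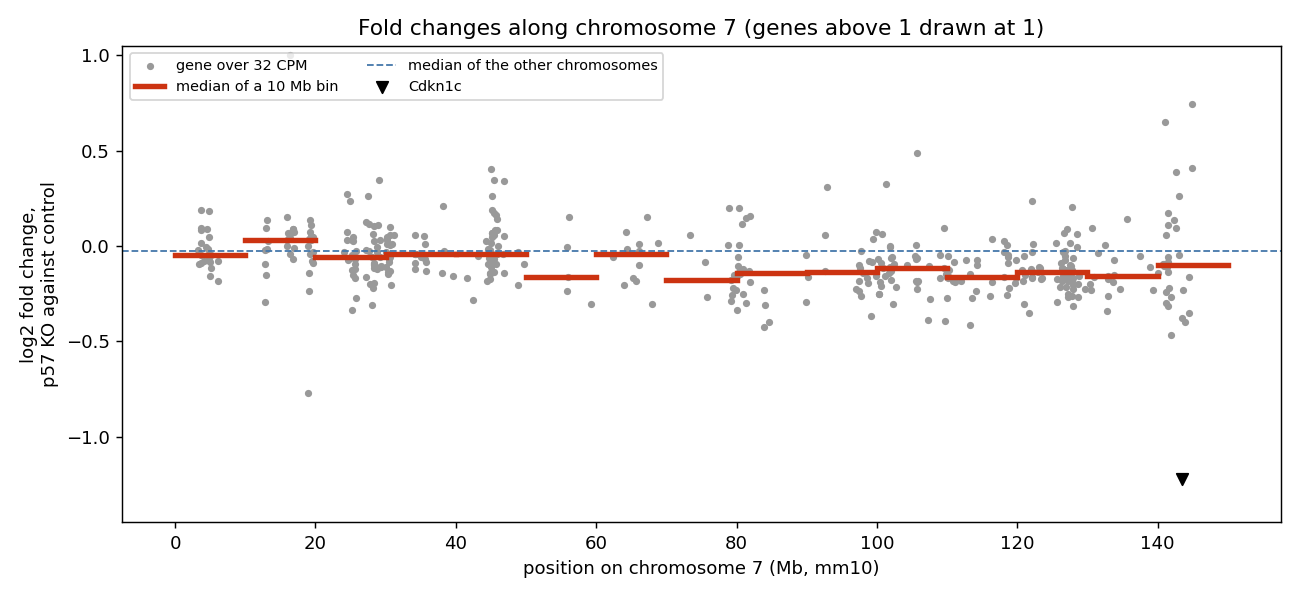
Log2 fold change (p57 KO against control) of genes over 32 CPM by position on chromosome 7 in Mb; grey points are genes, red bars are medians of bins of 10 Mb, and the dashed line is the median of the other chromosomes. From 70 Mb on, the bin medians lay between -0.18 and -0.10, and from 60 to 70 Mb it was -0.04.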

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

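The settings with the fibroblast score as a covariate and without the genes of chromosome 7 were chosen after the data were seen. The fall of Cdkn1c passed with RLE factors, the other filters, the block, the fibroblast score, limma-voom and DESeq2, and without each library. Over the fits without 1 library its log2 fold change ran from -1.27 to -1.19. It was not read for the test against a fold of 1.2, nor without chromosome 7, on which it lies. Without 1 library, 2358 to 4029 genes changed, 1180 to 2136 of them higher and 1178 to 1893 lower, and 5 to 7 lists passed. DESeq2 called 2453 genes, of which 1102 were lower against 1725 in edgeR; the cause was not tested. Against a fold of 1.2, 469 genes passed. With the fibroblast score as a covariate 374 genes passed, 225 higher and 149 lower, and 3 lists (p53 targets, interferon response and self-renewal); the covariate takes a degree of freedom and differs between the groups, and how much each contributed was not tested. Of 113 named genes besides Cdkn1c, 35 then kept direction and call and 75 kept direction alone. Cdkn2a (-0.014), Plk1 (-0.000237) and Thy1 (-0.11) turned to negative values from rises, none of them called. Thy1, like Tagln, Acta2 and Pdgfra, is averaged into the score, so the model takes up its rise by construction. For Cdkn2a and Plk1 the cause was not tested. Lists passing numbered 10 with no filter on low counts, 13 with fry and 0 with camera's estimated correlation. The cause was not tested. Fry does not compare a list with other genes, and it did not call the mitosis list. Unlike camera, it called the lists of apoptosis, integrated stress and BMP and related targets upwards and that of DNA repair downwards. The same held for the tested members of the Sertoli, the Leydig and peritubular, and the macrophage and leukocyte lists, upwards, and of the endothelial list, downwards. Without chromosome 7 there were 3105 changed genes, 1620 higher and 1485 lower. Of the named genes 29 lost their call without at least 1 library and 12 under DESeq2. Same-numbered libraries had correlations of 0.36, 0.08 and -0.16 in their deviations from the group means, and not every library correlated best with its own number. Such deviations cancel out within each group of 3, which partly fixes the signs. Whether the numbers pair the libraries therefore stays open. With the replicate number as a block 3706 genes changed, 1934 higher and 1772 lower, and no call of a named gene or list was lost. RLE factors gave 3430 genes, the stricter filter 3294, no filter 3931 and limma-voom 3338. At this depth 49.3% of genes changed 1.2-fold were recovered in a simulation with fewer changed genes than were called here. Smaller changes may therefore often have been missed.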

Other observations

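The families in this paragraph and the next were looked at after the data were seen. Ribosomal protein genes were higher in p57 KO by a small amount: of 82 tested, 59 rose and 1 fell, with a median log2 fold change of 0.15. Replication-dependent histone genes, whose RNA mostly lacks a poly(A) tail, rose in 15 of 29 cases with 0 falling, and their median was 1.07. The ribosomal RNA region transcripts Gm26917 and Gm42418 also took larger shares of the counts in every p57 KO library (0.416% to 0.543% and 0.245% to 0.286%, against 0.1% to 0.116% and 0.11% to 0.125% in control), so a difference in RNA selection was not excluded. Host genes of small nucleolar RNAs rose in 5 of 18 cases with 1 falling, with Zfas1 at 1.15 and Snhg12 at 1.12. Camera with an estimated correlation gave adjusted p of 0.0387, 0.0161 and 0.0387 over these 3 families, which are too small in that the families were picked by their values. Under the fibroblast covariate 27 ribosomal protein genes, 4 histone genes and 3 host genes rose, with medians of 0.15, 0.84 and 0.16. Reads shared with copies and pseudogenes make single members of the first 2 families uncertain.

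Ddit4, an inhibitor of the growth kinase mTORC1, had the smallest p of all genes and rose from 50.2 to 105 CPM (log2 fold change 1.07, SE 0.04, edgeR adjusted p = 8.58e-14). Gadd45b rose by 1.79 as log2, Exoc4 by 0.62 and Fat1 by 0.46. Neb, the gene of the muscle protein nebulin, rose from 28.9 to 57.8 CPM. Nanos2 and Mypop, both lower, lie next to each other on chromosome 7 with 2282 bp between them. Iqcn and Pde4c on chromosome 8 are 6069 bp apart, and their log2 fold changes were 2.93 and -0.93.

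In what follows, the tests of position in the genome, that of the segment genes at or under 32 CPM among them, of marker correlation and of regrouped libraries for the counts of genes were chosen after the result was seen. Genes of distal chromosome 7 were lower in p57 KO in median, though from 60 to 70 Mb 12 genes had a difference of -0.02 from other chromosomes (log2 fold change quartiles -0.17 and 0.01). Explanations by GC content, gene length, expression level and RNA of fibroblasts are argued against. After regression on GC content, gene length and expression level the difference from other chromosomes was -0.11 (95% bootstrap interval -0.13 to -0.10). It was -0.12 (-0.13 to -0.10) with the fibroblast score as a covariate. On other chromosomes 0 of 21 runs of neighbouring genes had a median as low. A run held as many genes as the segment, or a whole chromosome where that held fewer. The segment was picked by its low values, so this comparison cannot decide on chance position. A candidate explanation is that fewer copies of distal chromosome 7 are present in part of the p57 KO cells, which would lower genes of any level. The 333 segment genes at or under 32 CPM had a difference of -0.13 (-0.16 to -0.09). These genes lie in the same segment, which was picked by its low values, and another cause acting on the segment would lower them too. Their difference therefore cannot decide for fewer copies. A loss of 1 of 2 copies in about 14.7% of cells would give the size seen, and a gain in the control cells would give the same ratio, so the count data leave the direction, and any link to Cre at the Cdkn1c locus, open.

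Fibroblast and feeder cell markers were higher in p57 KO. Within groups they moved together, with a mean pairwise correlation of 0.848 while the central 95% of random lists of like size and level reached at most 0.0757. This may reflect more fibroblast or feeder cells in the p57 KO libraries, although the cells were passed over a Sephadex column, and abundant markers such as Fn1 (414 CPM in control, 842 CPM in p57 KO) and Vim (57.9 and 181 CPM) were present in both groups. Expression of these genes in the germ cells cannot be told apart from it: 100% of marker pairs correlated positively within groups, which a varying response of the same cells would give too. All 24 markers were measured in the control libraries, and Dcn is also in the list of imprinted genes.

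For the p53 targets and interferon genes, the fibroblast score was tested as the cause of the rise, with 50% of each list's median as the bound. With the score as a covariate the median of the p53 targets was 0.31 (95% bootstrap interval 0.24 to 0.49), above the bound of 0.25, and that of the interferon genes 0.22 (0.11 to 0.47), below the bound of 0.28, but each bound lies inside its interval. More fibroblast or feeder cells and a rise in the germ cells therefore cannot be told apart for either list, and the score itself differs between the groups. Exposure to the virus or to Cre itself also stays open for both lists, since 0 libraries are described as having a virus without Cre or Cre without floxed alleles. The loss of Cdkn1c is the biological difference that the design names, and it was not separated from these.

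The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split puts control and p57 KO libraries on each side, so the group difference adds to the spread and holds gene calls down. The gene counts of those splits therefore cannot decide whether the grouping arose by chance. For changed genes, 1 split, the real one, gave 3450, and the highest of the others 0. For genes higher and for genes lower, 1 split, again the real one, gave 1725, and the highest of the others 0. For lists passing camera, 3 splits gave 6 or more, the real one with 6 among them, and the highest of the others gave 7.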
